A study of Mus musculus with 4 samples.

How the data were processed

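Total RNA from primary cortical neural stem cells of newborn mice was sequenced from libraries made with a BGI kit, per the labels' protocols. The 4 libraries fall into 4 groups with 1 library per group: Ctrl and iKO in growth medium (day 0) and Ctrl and iKO after withdrawal of EGF and bFGF (day 3). Groups were taken from the sample titles and genotype labels. The labels name a recombinase in the genotype of the iKO libraries and none in that of the Ctrl libraries. Treatment with an inducer is not given in the sources used here.

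The deposited files hold 1 row per RefSeq transcript, 55122 in each library, with an expected count and an expression value. HISAT, Bowtie2 and StringTie are named with the mm10 build, per the submitters' processing notes, without versions. The tool that made the expected counts, the annotation release and any filter are not given in the sources used here. The expected counts deposited by the authors are estimates with decimals. The unit of the deposited expression value is not named in the header, and it was taken as FPKM because its ratio to the count and the transcript length was nearly constant within a library. The authors' deposited tables of differential genes give a log2 ratio of iKO to Ctrl and an FDR, per the file headers. That log2 ratio was within 0.005 of the ratio of summed FPKM for 85.8% of the day 3 genes checked. The p-value method behind the deposited FDR is not given in the sources used here, and each table compares 2 libraries, so its FDR does not measure spread between cultures.

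Expected counts were summed over the transcripts of each gene (17621 genes) and rounded for scaling. Symbols came from a RefSeq table of GRCm38.p6, the same build, for 17498 gene IDs and from the authors' tables for 19, and 104 IDs had none. Effective library sizes were computed with edgeR 4.0.16 (TMM) in R 4.3.3. TMM factors were 0.966 for Ctrl and 1.06 for iKO at day 0, and 1.02 and 0.962 at day 3. The most abundant gene held between 0.759% and 1.16% of a library. The log2 ratio was log2((CPM1 + 1)/(CPM2 + 1)), which understates ratios of low genes. Genes with a mean of at least 1 CPM over the 4 libraries were compared, which left out 4645. The printed fold is the ratio of CPM without the pseudocount, with an exact conditional (Clopper-Pearson) 95% interval of the rounded counts computed with scipy 1.17.1. Reads are not independent molecules, so intervals and floors cover counting error only. The floor was 3 counts per library. No test across conditions was run. A model of genotype and day without their interaction would leave 1 residual degree of freedom and take the difference between the days as error, and it was not fitted.

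Chosen before the data were examined were the comparisons, the 28 gene lists, the alternatives and the rule for named genes. The rule takes, per comparison, Seh1l and Cdkn1a, the 8 largest log2 ratios in each direction among named genes, and the 2 members of each list with the largest ratios. It takes 5 genes in each direction for the difference between days. The lists are markers of neural stem and progenitor cells, intermediate progenitors and neurons, the GABAergic lineage, astrocytes, the oligodendrocyte lineage, microglia, endothelium, fibroblasts and mural cells and ependyma. The others are mitosis, DNA replication, CDK inhibitors, p53 targets, Y complex and other nucleoporins, GATOR2 partners, the ATF4, immediate early, EGF and FGF, interferon, inflammation and secretory, Notch, BMP, cholesterol and hypoxia lists, and 3 symbol families. The mitochondrial family had 0 genes in the files and the ribosomal family takes in Rps27l and the kinase Rps6ka1 by its symbol rule. Lists share few members: the Notch and neural stem lists share 3, and 5 other pairs share 1 each. A few listed symbols were not analysed here. The text gives values for part of the genes that the rule takes, and 1 gene is not reported here. The median of a list was set beside the medians of 10000 random lists of the same size matched on deciles of mean expression, as a description of these libraries. Of 25 lists with a median, 14 lay outside the central 95% for iKO against Ctrl at day 0 and 17 at day 3. For day 3 against day 0 the counts were 15 in Ctrl and 16 in iKO. Random lists do not keep together genes that vary together, so a place outside the range does not by itself set a list apart.

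Alternatives were pseudocounts of 0.1 and 5 CPM, no minimum or a minimum of 5 CPM, library totals, DESeq2 1.42.0 size factors, deposited FPKM, and scaling without ribosomal protein and histone genes. The ratio code was tested on simulated Poisson counts with 200 altered genes among 12977. For the day 3 comparison of iKO and Ctrl, the intervals covered the true ratio for 95.5% of genes. There, 62 of 66 genes altered 4-fold passed the 2-fold threshold, as did 20 of 67 altered exactly 2-fold and 0 of 12777 unaltered genes. The same simulation for day 0 gave 65 of 66, 20 of 67 and 0 of 12777. It holds counting error and no spread between cultures, so it does not show how often unaltered genes pass 2-fold in real cultures.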

Results

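RNA was sequenced from primary neural stem cells grown from the cortex of newborn mice, to ask how loss of Seh1 alters gene expression while the cells proliferate and after they are set to differentiate. Seh1, encoded by Seh1l, is a nucleoporin of the Y complex of the nuclear pore and also a member of the GATOR2 complex, which regulates mTORC1. Control cells (Ctrl) carried floxed Seh1 alleles, and depleted cells (iKO) carried the same alleles with a recombinase fused to an estrogen receptor domain, a form used for inducible deletion. Cells were sampled in growth medium with EGF and bFGF (day 0) or after these factors were withdrawn (day 3). The 4 libraries held 1 library per group, with totals of 21040590 expected counts for Ctrl and 20625897 for iKO at day 0, and 19745921 and 19611788 at day 3. No comparison therefore has a replicate check, and no p-value was computed. Intervals are 95% intervals of counting error only, and levels are in CPM after TMM scaling. A gene was counted as higher or lower when it differed by at least 2-fold on the log2(CPM + 1) scale among 12976 genes with a mean of at least 1 CPM.

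The targeted gene was lower in both iKO libraries. Seh1l (gene ID 72124, chromosome 18, 67774876 to 67795487, GRCm38) was at 40.3 CPM in Ctrl and 19.2 CPM in iKO at day 0, 2.10-fold lower (1.86 to 2.37). At day 3 it was at 33.2 CPM in Ctrl and 11.0 CPM in iKO, 3.01-fold lower (2.58 to 3.54). Counts cover the whole transcript, and which exons were floxed is not given in the sources used here, so the counts may include transcripts that lack the deleted part. Esr1 (gene ID 13982, chromosome 10, 4611989 to 5005633) had 1 count in Ctrl and 1924 in iKO at day 0, and 2 and 2311 at day 3. Its ratios were 1795 (322 to 70929) at day 0 and 1231 (340.5 to 10173) at day 3. Esr1 was the only gene at least 10-fold higher in both iKO libraries than in both Ctrl libraries at 2 CPM or more. In counts rounded to whole numbers, the Esr1 transcript with the full 3' UTR held 3 of 1924 in iKO at day 0, 0.156% (0.0322 to 0.455, exact Clopper-Pearson), and 2 of 2311 at day 3, 0.0865% (0.0105 to 0.312). Before rounding it held 3.05 and 1.53 expected counts, and nearly all others lay on 1 short transcript model.

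**Figure D1:**
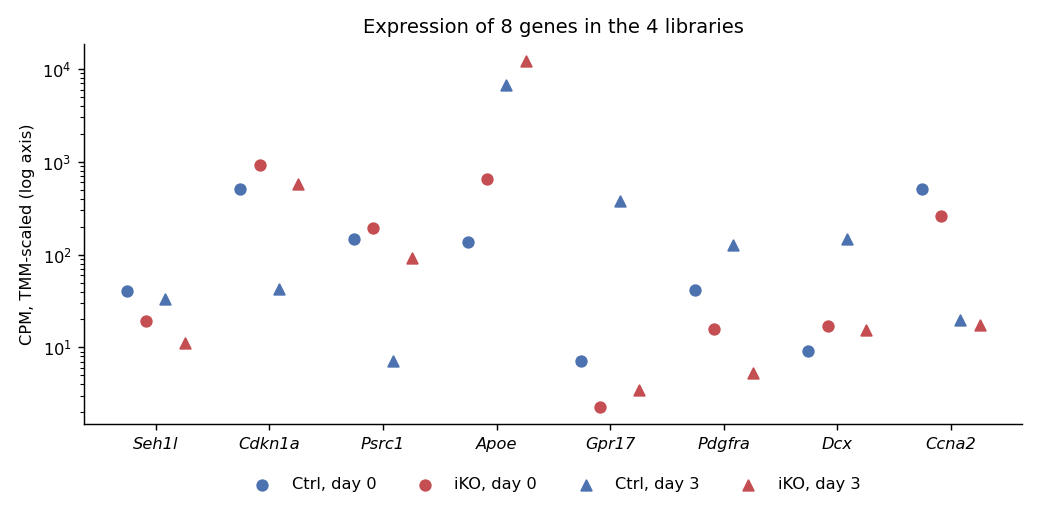
Levels of 8 genes in the 4 libraries, in CPM on a log axis, with 1 point per library (blue Ctrl, red iKO, circles day 0, triangles day 3). Seh1l lies lower in iKO at both days, and Cdkn1a reads 43.1 CPM in Ctrl and 578 CPM in iKO at day 3.

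In control cells, withdrawal of the growth factors went with lower cell cycle genes and higher glial genes. All 25 mitosis genes and all 25 DNA replication genes were at least 2-fold lower at day 3, with median log2 ratios of -4.10 and -3.24. Ccnb1, the cyclin of mitotic entry, was at 322 CPM at day 0 and 10.3 CPM at day 3, 31.3-fold lower (27.3 to 36.1). Rrm2, a subunit of ribonucleotide reductase, was 31.0-fold lower (28.2 to 34.2). Of 16 astrocyte genes 14 were higher and 1 lower, with a median of 3.14. Apoe was at 138 CPM at day 0 and 6764 CPM at day 3, 49.0-fold higher (47.2 to 50.9), and Gfap was 40.7-fold higher (32.6 to 51.5). Of 14 oligodendrocyte lineage genes 11 were higher (median 1.71), with Gpr17, a receptor of committed precursors, 53.1-fold higher (45.0 to 63.0). Of 19 neuronal genes 6 were higher and 2 lower (median 0.72), and of 7 GABAergic genes 6 were higher (median 1.37). With no minimum level the neuronal median was 0.34, inside the range of random lists. Dcx, a microtubule protein of young neurons, was 16.2-fold higher (14.0 to 18.9), whereas Gap43 was 12.5-fold lower (11.0 to 14.3).

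The same comparison in control cells showed lower growth factor targets and p53 targets at day 3. Of 14 EGF and FGF response genes 7 were lower (median -1.33), among them Ccnd1 by 17.4-fold (16.8 to 18.1) and Spry4 by 7.37-fold (6.90 to 7.88). Of 30 p53 targets 17 were lower and 3 higher (median -1.26). Cdkn1a, the gene of the CDK inhibitor p21 (gene ID 12575, chromosome 17, 29090979 to 29100722), was at 513 CPM at day 0 and 43.1 CPM at day 3, 11.9-fold lower (11.1 to 12.8). Of 93 ribosomal protein symbols 73 were lower (median -1.21), and 6 of 9 Y complex nucleoporins and 12 of 19 other nucleoporins were lower (medians -1.43 and -1.14). On the log2(CPM + 1) scale the largest ratios belonged to Shisa9, an AMPA receptor auxiliary protein, at 190-fold higher (117 to 333), and Rab26, a vesicle GTPase, at 483-fold lower (207 to 1489). In all, 1892 genes were higher and 1954 lower, with library totals 2061 and 1784, and with a pseudocount of 5 CPM 1213 and 1498.

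In growth medium, depleted cells had higher p53 targets and astrocyte genes and lower cell cycle genes. Of 30 p53 targets 9 were at least 2-fold higher and 29 lay above 0, with a median log2 ratio of 0.78, outside the central 95% of medians of random lists matched on expression (-0.23 to 0.04). Perp was at 2.41 CPM in Ctrl and 16.8 CPM in iKO, 6.97-fold higher (5.16 to 9.59), and the death receptor gene Fas was 4.86-fold higher (3.89 to 6.13). Cdkn1a was at 513 CPM in Ctrl and 926 CPM in iKO, 1.81-fold higher (1.76 to 1.85). Of the 7 CDK inhibitors, however, 5 lay below 0 and none differed by 2-fold (median -0.41, random lists -0.36 to 0.25), with Cdkn2c 1.82-fold lower (1.71 to 1.93). Of 16 astrocyte genes 4 were higher and 15 lay above 0 (median 0.66, random lists -0.29 to 0.10). Apoe was at 138 CPM in Ctrl and 656 CPM in iKO, 4.75-fold higher (4.56 to 4.95), and Clu was 4.50-fold higher (4.03 to 5.05). All 25 mitosis genes and all 25 replication genes lay below 0, by less than 2-fold except for Chaf1a, with medians of -0.73 and -0.77 against random ranges of -0.25 to 0.03 and -0.25 to 0.06. Cdca8, a subunit of the chromosomal passenger complex, was at 179 CPM in Ctrl and 97.6 CPM in iKO, 1.83-fold lower (1.74 to 1.94).

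Lineage markers at day 0 differed less evenly. Of 14 oligodendrocyte lineage genes 4 were lower, led by Sox10, the lineage's transcription factor, at 3.13-fold (2.62 to 3.76) and Pdgfra, the receptor of its precursors, at 2.65-fold (2.33 to 3.01). The list's median of -0.28 lay just outside the random range (-0.27 to 0.15). It lay inside the random range under 3 of the 8 alternative settings. Of 19 neuronal genes 2 were higher, Stmn2 at 3.61-fold (2.61 to 5.09) and Neurod1 at 3.31-fold (1.99 to 5.74), and the median was 0.24 (random lists -0.24 to 0.17). That median lay inside the random range under 2 of 8 settings. All 7 GABAergic genes lay above 0 (median 0.84), with Gad1, an enzyme of GABA synthesis, 2.52-fold higher (2.19 to 2.91). All 17 cholesterol synthesis genes lay below 0 (median -0.70), and Lss was 2.03-fold lower (1.94 to 2.12). All 9 remaining Y complex nucleoporins lay below 0 with none at 2-fold (median -0.52), and 18 of 19 other nucleoporins did so (median -0.38). Of 93 ribosomal protein symbols 87 lay below 0 (median -0.36, random lists -0.20 to -0.05), with 1 at least 2-fold higher. Of 5 measured fibroblast and mural genes 3 were higher (median 1.32), including Acta2 at 10.3 CPM in iKO and 2.47 CPM in Ctrl. That median ranged from 0.31 to 1.97 over the alternative settings, lowest with no minimum level. Of 4 ependymal genes 2 were higher (median 0.79), including Foxj1 at 2.03-fold (1.89 to 2.19). The ependymal median lay inside the random range with a pseudocount of 0.1 CPM.

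At day 0, 347 genes were higher and 43 lower in iKO. The counts were 469 and 25 with library totals, 248 and 20 with deposited FPKM, 706 and 78 with a pseudocount of 0.1 CPM and 111 and 13 with one of 5 CPM. After Esr1, the largest higher ratios on the log2(CPM + 1) scale, in that order, were those of Ass1, an enzyme of arginine synthesis, at 14.2-fold (10.9 to 18.8), Rpl34, the cholesterol exporter gene Abca1 at 5.57-fold (5.07 to 6.12), Perp, Hmcn2, Car10 and Gbp9. The largest lower ratios on that scale were those of Ahcy, Cpne8 at 4.11-fold (3.61 to 4.71), Fgf14, H2ac19, Sox10, H2ac24, Syt6 and Moxd1. Rpl34, the H2a histone genes and Ahcy share sequence with copies elsewhere in the genome, so their counts are uncertain. Rpl34 was at 8.70 CPM in Ctrl and 56.9 CPM in iKO while Rpl34-ps1 was at 206 CPM and 108 CPM. H2ac19 was at 2.06 CPM and 0 while H2ac18 was at 0.772 CPM and 7.20 CPM.

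After growth factor withdrawal, the p53 targets stood further apart. Of 30 targets 25 were at least 2-fold higher in iKO at day 3 and none lower, with a median of 1.65 (random lists -0.20 to 0.18). Cdkn1a was at 43.1 CPM in Ctrl and 578 CPM in iKO, 13.4-fold higher (12.5 to 14.4). Psrc1, a spindle protein gene that p53 also regulates, was 13.0-fold higher (10.9 to 15.5). The CDK inhibitor Cdkn1c went the other way, 8.60-fold lower (7.05 to 10.6). Of the 7 CDK inhibitors 2 were higher and 1 lower (median 0.15). The cell cycle lists did not stand apart at this stage: none of the 25 mitosis genes or 25 replication genes differed by 2-fold, and their medians of -0.16 and 0.05 lay within the ranges of random lists.

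Oligodendrocyte and neuronal genes were lower in depleted cells at day 3, and astrocyte genes were higher. Of 14 oligodendrocyte lineage genes 11 were lower and none higher, with a median of -1.82 (random lists -0.29 to 0.29). Gpr17 (gene ID 574402, chromosome 18, 31942999 to 31949890) was at 376 CPM in Ctrl and 3.44 CPM in iKO, 109-fold lower (85.5 to 141). Pdgfra (gene ID 18595, chromosome 5, 75151322 to 75198206) was 24.4-fold lower (20.0 to 30.2) and Sox10 21.4-fold lower (17.8 to 26.0). Olig1 and Olig2, which progenitors also express, were among the 3 members that differed by less than 2-fold. They are named here after their values were seen, with log2 ratios of -0.05 for Olig1 and -0.55 for Olig2. Of 19 neuronal genes 8 were lower and none higher (median -0.74, random lists -0.26 to 0.29), with Dcx 9.58-fold lower (8.49 to 10.9) and Ina, a neurofilament gene, 6.46-fold lower (5.34 to 7.88). Of 7 GABAergic genes 3 were lower (median -0.76, random lists -0.42 to 0.53), with Dlx1 12.1-fold lower (9.17 to 16.2). With a minimum of 5 CPM the GABAergic median was -0.34, inside the random range, and with a pseudocount of 5 CPM it was -0.41. Of 16 astrocyte genes 4 were higher and none lower (median 0.79, random lists -0.28 to 0.29), with Cd44 4.13-fold higher (3.58 to 4.78) and Clu 3.35-fold higher (3.24 to 3.45). Unlike most of the list, Cd44 was lower at day 3 than at day 0 in Ctrl (11.9 CPM against 86.2 CPM). The 2 astrocyte genes below 0, named after their values were seen, were Aldh1l1 (-0.49) and Aldoc (-0.09). Of 4 ependymal genes 3 were higher (median 1.15), and Foxj1, a transcription factor of ciliated cells, was 3.91-fold higher (3.69 to 4.16). The ependymal median ranged from 0.50 to 1.66 over the alternative settings.

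**Figure D2:**
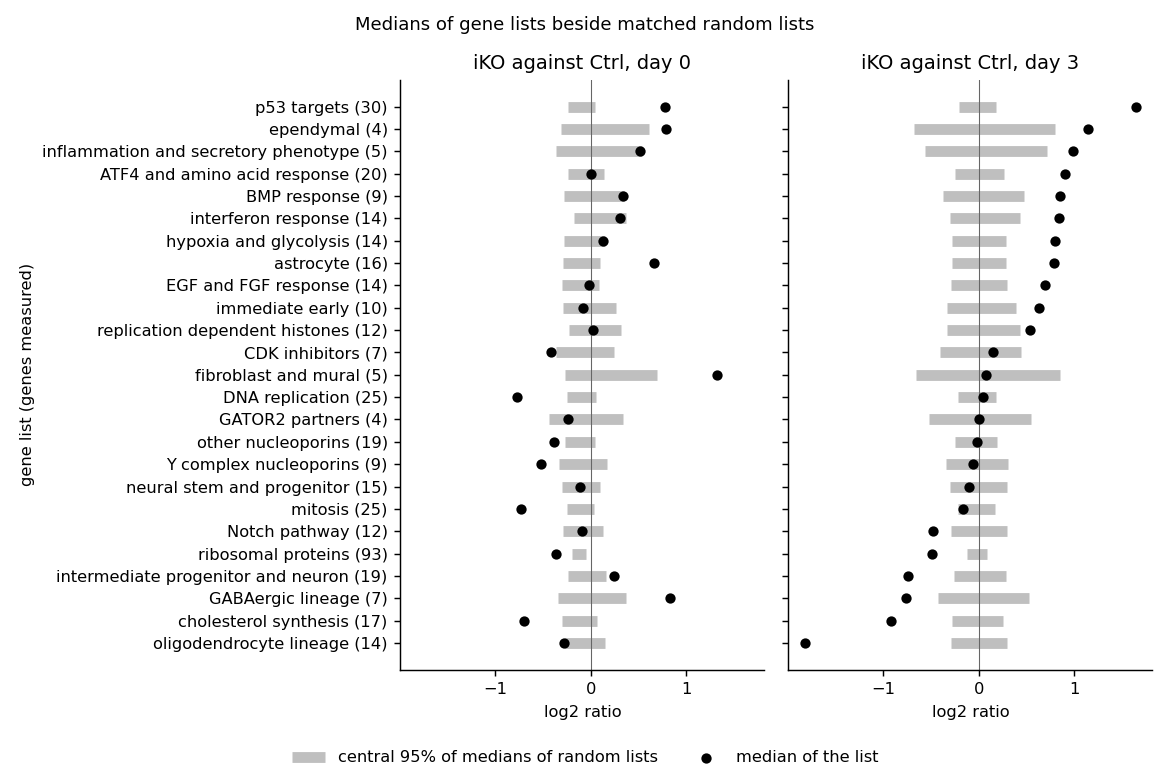
Median log2 ratio of iKO against Ctrl for 25 gene lists at day 0 and day 3 (black points), beside the central 95% of medians of 10000 random lists matched on expression (grey bars). At day 3 the p53 targets lie at 1.65 and the oligodendrocyte lineage at -1.82.

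Stress and signalling lists were higher at day 3 in iKO. All 20 genes of the ATF4 and amino acid response lay above 0 and 9 were at least 2-fold higher (median 0.90, random lists -0.25 to 0.26). Chac1, which degrades glutathione, was 8.35-fold higher (5.89 to 12.2), and the transcription factor gene Atf5 was 4.95-fold higher (4.58 to 5.36). At day 0 the same list had a median of 0.01 with 1 higher gene. Of 14 interferon response genes 6 were higher (median 0.85), with Ifit3 4.06-fold higher (3.24 to 5.14). Of 14 EGF and FGF response genes 5 were higher and 2 lower (median 0.69), and the ERK phosphatase gene Dusp6 was 4.49-fold higher (4.20 to 4.80) in medium that lacked both factors. Dusp6 nevertheless read less at day 3 than at day 0, at 240 against 438 CPM in iKO and 53.4 against 309 CPM in Ctrl. From day 0 to day 3 this list had 5 lower and 0 higher genes in iKO (median -0.60). Of 14 hypoxia and glycolysis genes 4 were higher (median 0.80). Of 10 immediate early genes 4 were higher and 1 lower (median 0.63). Of 9 BMP response genes 2 were higher (median 0.85), Smad9 at 4.62-fold (3.79 to 5.66) and Id1 at 3.82-fold (3.40 to 4.30). Of 5 measured genes of the inflammation and secretory list 2 were higher (median 0.99), with Igfbp3 at 1549 CPM in iKO and 232 CPM in Ctrl. Over the alternative settings the medians ranged from 0.34 to 2.18 for the inflammation and secretory list, 0.31 to 0.98 for immediate early genes, 0.43 to 0.93 for the BMP list and 0.52 to 1.02 for the interferon list, all outside the ranges of random lists where the setting gave a value.

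The cholesterol synthesis and Notch pathway lists had medians below the ranges of random lists at day 3. All 17 cholesterol synthesis genes lay below 0 and 6 were lower (median -0.92), with Idi1 3.34-fold lower (2.86 to 3.91). Of 12 Notch pathway genes 4 were lower and 1 higher (median -0.48), with Hes5 7.32-fold lower (6.46 to 8.31) and the ligand gene Dll3 6.63-fold lower (6.07 to 7.26). Of 93 ribosomal protein symbols 85 lay below 0 (median -0.48, random lists -0.13 to 0.09), with 1 at least 2-fold lower and 2 higher. Of 12 measured replication dependent histones 3 were higher and none lower (median 0.54, random lists -0.33 to 0.43), but with no minimum level the median was 0.02, inside the random range. The neural stem and progenitor list had 1 of 15 genes higher and 1 lower (median -0.10). Medians were -0.06 for the Y complex, -0.02 for other nucleoporins, 0.00 for the 4 GATOR2 partners and 0.08 for the 5 fibroblast and mural genes. Microglial markers were too few to summarise, with 2 measured genes and a list total of at most 12.2 CPM in any library. The endothelial list had 1 measured gene and a total of at most 11.2 CPM. In all, 815 genes were higher and 620 lower. With library totals in place of TMM the counts were 684 and 699, with deposited FPKM 469 and 458, and with a pseudocount of 5 CPM 431 and 358. The largest higher ratios after Esr1 on the log2(CPM + 1) scale, in that order, were those of Klhdc7a, Ass1 at 42.9-fold (22.3 to 94.5), the matrix protein gene Ogn, Cdkn1a, Psrc1, Ddit4l and the peptide gene Apln. The largest lower ratios on that scale were those of Gpr17, the matrix protein gene Tnr at 22.7-fold (20.9 to 24.6), Grik3, Pdgfra, Sox10, Plxnb3, Vxn and Pcdh15.

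**Figure D3:**
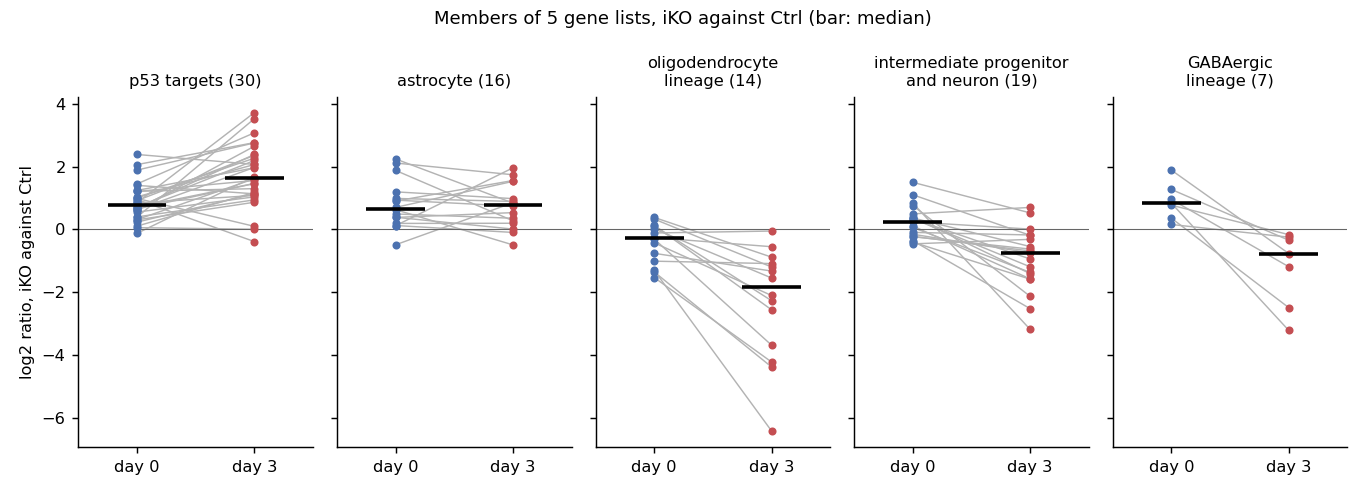
Log2 ratios of iKO against Ctrl for each measured member of 5 lists, with day 0 in blue and day 3 in red, grey lines joining the same gene and black bars at the medians. The medians of the oligodendrocyte list are -0.28 and -1.82, and those of the neuronal list 0.24 and -0.74.

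The log2 ratios of iKO to Ctrl at the 2 days were set beside each other. Across genes, which are not independent replicates, the log2 ratios had a Pearson correlation of 0.44 and a Spearman correlation of 0.43, and the compared ratios share no library. Of the genes higher at day 0, 165 were also higher at day 3, where 21.8 would be shared by independent lists. Of those lower at day 0, 18 were also lower at day 3 against 2.05. With 1 library per group, neither the correlation nor these overlaps separate loss of Seh1 from another lasting difference between the Ctrl and iKO cultures. The day 3 log2 ratio exceeded the day 0 ratio by at least 1 for 481 genes and lay below it by at least 1 for 714. In all 1195 genes differed in this way, against 596 with a pseudocount of 5 CPM and 790 with deposited FPKM. Apln had the largest positive difference at 3.63, followed by Ahcy, Psrc1, Ddit4l and Anxa3. Gpr17 had the largest negative difference at -5.10, followed by Scg2, Tnr, Dlx1 and Dcx. By list, the median difference was 0.83 for p53 targets, -1.62 for the oligodendrocyte lineage, -1.18 for neuronal genes, -2.14 for GABAergic genes, -0.16 for astrocyte genes and 0.95 for the ATF4 list. It was 0.59 for mitosis and 0.84 for DNA replication, with all 25 genes of each above 0. These differences were not tested, since each rests on 4 single libraries.

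In depleted cells astrocyte genes were also higher at day 3, while the medians of the oligodendrocyte and neuronal lists lay below those in Ctrl. From day 0 to day 3, 13 of 16 astrocyte genes were higher in iKO (median 2.97), and Apoe read 656 CPM and 12096 CPM, 18.4-fold higher (18.1 to 18.8) against 49.0-fold in Ctrl. For 10 of the 16 astrocyte genes the stage log2 ratio was smaller in iKO than in Ctrl, and the median difference of -0.16 lay below the random range (-0.13 to 0.33). The oligodendrocyte list had 2 higher and 3 lower genes (median 0.12), the neuronal list 1 higher and 7 lower (median -0.39), and the GABAergic list 4 lower and none higher. The neuronal median lay inside the random range as reported and outside it under 4 of 8 alternative settings, and the GABAergic median lay outside it as reported and inside it under 3. Cspg4, a proteoglycan of oligodendrocyte precursors, was 3.66-fold lower (3.35 to 4.00). All 25 mitosis and all 25 replication genes were lower (medians -3.77 and -2.46). Of 30 p53 targets 7 were lower and 2 higher (median -0.35), and Cdkn1a was 1.60-fold lower (1.56 to 1.64). On the log2(CPM + 1) scale the largest ratios were those of Shisa9 at 27.8-fold higher (22.2 to 35.2) and Tnc at 106-fold lower (91.8 to 124). In all, 1459 genes were higher and 1486 lower, and with deposited FPKM 904 and 1447. With library totals in place of TMM, 39.8% of these calls were higher, and with deposited FPKM 38.5%, against 49.5% as reported.

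The stage log2 ratios of iKO and Ctrl had a Pearson correlation of 0.84 across genes and a ratio of SDs, iKO over Ctrl, of 0.84. Genes at least 2-fold higher in Ctrl had a median share of 71.3% of their log2 ratio in iKO, and those lower 74.7%. Selected instead on iKO, the shares in Ctrl were 92.6% and 110.3%. The share depends on the condition used to select, and in both directions it was smaller with selection on Ctrl. Across genes the stage log2 ratios also had a smaller SD in iKO (0.971) than in Ctrl (1.15), each from single libraries. Of the genes higher in Ctrl, 1044 were higher in iKO (213 for independent lists), and of those lower, 1175 were lower (224 for independent lists).

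**Figure D4:**
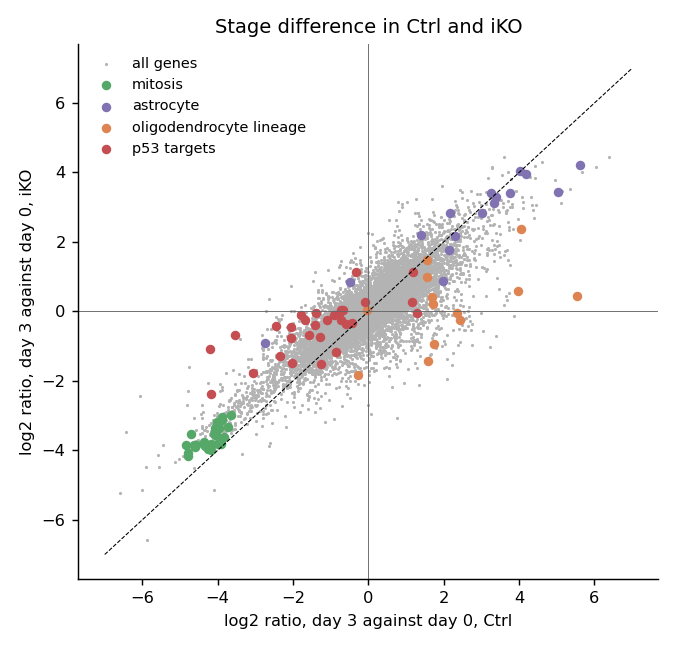
Log2 ratio of day 3 against day 0 in Ctrl (horizontal axis) and iKO (vertical axis) for 12976 genes (grey), with the dashed line at equal values. Members of 4 lists are coloured, and the oligodendrocyte genes have a median of 1.71 in Ctrl and 0.12 in iKO.

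The authors' deposited table for day 3 lists 1774 genes, 911 higher and 863 lower in iKO. All 1774 had the same sign in the counts used here, and of the 1666 with a mean of at least 1 CPM, among 12976 genes compared, 1374 differed by at least 2-fold. That table compares the same 2 libraries and lists only absolute log2 ratios of at least 1. Neither the agreement in sign nor the list counts that follow are therefore independent support. Among the lists, the authors' deposited table holds 24 of 30 p53 targets as higher, 12 of 15 oligodendrocyte lineage genes as lower, 10 of 25 neuronal genes as lower and 9 of 17 cholesterol synthesis genes as lower. It holds no mitosis or DNA replication gene. The authors' deposited table for day 0 could be used only in part, because it ends inside a number at gene ID 12332 of a list sorted by ID. The part read holds 103 genes, 91 higher and 12 lower. Within that range of IDs, 33 of the genes listed as higher at day 0 are also higher in the authors' deposited table for day 3, against 4.61 for independent lists.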

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

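All tests in this part were chosen after the results were seen. The neuronal list was higher in iKO at day 0 and lower at day 3, with median log2 ratios of 0.24 and -0.74, and the GABAergic list did the same with 0.84 and -0.76. These lists were singled out because their iKO to Ctrl ratios had opposite signs at the 2 days, a difference that was not tested. Over the alternatives the GABAergic median at day 3 ranged from -0.95 to -0.34 and lay inside the random range with a minimum of 5 CPM, and the neuronal median at day 0 ranged from 0.09 to 0.37 and lay inside it under 2 of 8. Of single genes, 8 differed by at least 2-fold in opposite directions: Chgb, Iqsec3, Islr2, Pcdha10, Rab3c, Rgs8, Ryr3 and Scg2, named after their values were seen. All were higher at day 0 and lower at day 3, where 16.6 would be shared by independent lists, and 0 genes went the other way against 2.70. Scg2, a granule protein gene, had log2 ratios of 1.11 at day 0 and -3.13 at day 3.

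The lower oligodendrocyte and neuronal lists at day 3, beside a higher astrocyte list, were set against 3 explanations. A difference already present at day 0 and carried along unchanged would leave the same ratio at both days. The upper quartile of the day 3 minus day 0 differences was -0.74 for the oligodendrocyte list and -0.43 for the neuronal list. In these libraries the ratio was thus lower at day 3 than at day 0 for most genes of those lists. The list medians at both days were known when this test was chosen. Quartiles across genes do not measure spread between cultures, so the test cannot decide on an unchanged difference. For the astrocyte list it stays open as well. At day 0, 4 of 14 oligodendrocyte genes were already at least 2-fold lower and 5 lay above 0. A difference present at day 0 that widened by day 3 therefore stays open. A general delay of the stage difference cannot be told apart here, with 1 day sampled after withdrawal. The day 3 minus day 0 differences of astrocyte genes had a median of -0.16, below the random range (-0.13 to 0.33) as a delay predicts. Their quartiles, however, lay on both sides of 0 (-0.37 and 0.28). All 25 mitosis and all 25 replication genes fell less in iKO, as a delay also predicts, but both lists were already lower in iKO at day 0. A delay alone also predicts stage ratios of the same sign in Ctrl and iKO. Of 7 GABAergic genes, however, 6 were higher at day 3 in Ctrl, against 0 higher and 4 lower in iKO. Stage medians in Ctrl and iKO were 0.72 and -0.39 for neuronal genes. They were 1.71 and 0.12 for oligodendrocyte and 3.14 and 2.97 for astrocyte genes. An equal delay of all lists does not predict these values, but with single libraries they cannot decide on it. Fewer cells of the oligodendrocyte lineage and lower expression in each cell cannot be told apart in bulk RNA, where both give the 11 lower genes, and a biological effect of Seh1 loss stays open.

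The p53 targets were higher in iKO at day 3. Library scaling is argued against by the lowest list median over the other scalings, 1.52. Transcript length is argued against by random lists matched on expression and length, among which the list's median lay at percentile 100. Activity of the recombinase apart from the loss of Seh1 cannot be told apart from that loss, because 0 control libraries carry a recombinase.

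Esr1 counts in both iKO libraries were weighed as reads from the estrogen receptor part of the recombinase transgene and as full-length endogenous mRNA. The transcript with the full 3' UTR held at most 0.156% of the rounded Esr1 counts, with an upper bound of 0.455% (exact Clopper-Pearson), which argues against full-length endogenous mRNA. The transgene is a candidate source, and a short endogenous isoform stays open.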

How the results depend on the processing

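All alternatives here were chosen before the data were examined. Of 106 values of comparison results under the alternatives, 91 stayed the same and 15 moved. Counts within 1.5-fold of the reported value, correlations and slopes within 0.1, and Seh1l inside its counting interval were called the same. Of the 91, 2 were the authors' deposited gene counts at an absolute log2 ratio of at least 1, which could not change. Of 776 list values, 745 kept their place inside or outside the random range, 16 entered it and 15 left it. Of 2095 values of named genes, 696 lay outside the gene's counting interval, which was computed without a pseudocount. This count does not measure movement alone: 56 values lay outside with no minimum, a setting that leaves each gene's ratio unchanged. A pseudocount of 0.1 CPM gave 706 higher and 78 lower genes at day 0, and one of 5 CPM gave 111 and 13, because a larger pseudocount shrinks the ratios of low genes. With 5 CPM, day 3 had 431 higher and 358 lower genes, the stage difference in Ctrl 1213 higher genes, Seh1l a log2 ratio of -1.25 at day 3, and 596 genes differed between the days against 1195 as reported. Library totals gave 25 lower genes at day 0, and deposited FPKM gave 20. FPKM also gave 469 higher genes in iKO at day 3, 904 higher genes for the stage difference in iKO, -0.88 for Seh1l at day 0 and 790 genes that differed between the days. The FPKM alternative used no TMM scaling. It kept a pseudocount and a minimum of 1 on values that summed to between 385233 (Ctrl, day 3) and 452779 (Ctrl, day 0) per library. How much each of these contributed to the FPKM differences was not tested. Library totals moved the median of all genes at day 0 from -0.06 to 0.06, FPKM to 0.04, and they moved that of the stage difference in iKO to -0.14 and -0.13. Library totals also turned the balance of higher and lower genes, to 684 and 699 for iKO at day 3 and to 2061 and 1784 for the stage difference in Ctrl. At day 3 the medians of the p53, oligodendrocyte, neuronal, astrocyte, ATF4 and cholesterol lists stayed outside the random range under 8 of 8 alternatives, with ranges of 1.42 to 1.68 for p53 targets and -2.18 to -1.54 for the oligodendrocyte lineage. No paired analysis of a reported comparison was possible because the groups compared share fewer than 2 replicates, and none could be left out. A fit of iKO against Ctrl over both days with day as a block was not run. At these depths 1 count equals up to 0.0530 CPM, so ratios of genes near 1 CPM rest on few counts.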

Other observations

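The test in this part was chosen after the result was seen. Trp53 itself was not higher in depleted cells: it was at 179 CPM in Ctrl and 139 CPM in iKO at day 0, and at 81.5 CPM and 67.4 CPM at day 3. It was named after its values were seen.

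The lower cell cycle lists in iKO at day 0 led to the hypothesis of a smaller share of cycling cells, which predicts that members are lower by a similar factor. The 25 mitosis genes had log2 ratios between -0.95 and -0.47 with an SD of 0.112, below the central 95% of SDs of random lists matched on expression (0.222 to 0.546). A narrow range was not particular to cell cycle genes: the 17 cholesterol synthesis genes lay between -1.01 and -0.50. The comparison with random lists therefore cannot decide on a smaller share of cycling cells. A similar repression of each gene within cells would give the same values and was not tested.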
